A study of Homo sapiens with 14 samples.

How the data were processed

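Gene expression was measured in whole peripheral blood of 7 patients with follicular lymphoma, a cancer of germinal centre B cells, once at baseline and once on day 15 of cycle 2 of combined treatment. Per the labels, lenalidomide, an oral drug that binds the cereblon ubiquitin ligase, was given at 20 mg per day on days 1 to 21 of 28-day cycles, and rituximab, an antibody against the B cell surface protein CD20, at 375 mg per square metre on day 1 of each cycle. Blood was collected into PAXgene tubes, which lyse cells and stabilise their RNA, so that RNA of red cells, platelets and all white cells was measured together. Per the labels' protocols, 1500 ng of RNA was cleared of globin transcripts, and 300 ng of the cleared RNA was amplified and labelled with biotin for hybridisation to 1-colour bead arrays.

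The deposited tables held, per the file headers, a mean bead signal for each probe and sample on a linear intensity scale, with no background subtraction or normalization seen in the values. They also held, per the file headers, a detection p-value for each probe and array, which compares the probe with the negative controls of that array. The signals came from GenomeStudio, per the submitters' processing notes, and its version was not given in the sources used here. The authors' value table was compared with the signals probe by probe, and 100% of its cells were equal to them, so it held the same intensity values with no log scale, no centring and the same direction.

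Of 47224 probes, 2 with missing signals were left out. Signals were corrected for background and normalized with neqc of limma 3.58.1 in R 4.3.3, which fits a normal and exponential model of background and signal from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. A probe was tested if its detection p was under 0.05 on at least 7 of the 14 arrays, which left 15654 probes. Gene names came from the platform annotation matched to the RefSeq gene table through Entrez identifiers. Of the other 47222 probes, 30106 had 1 gene symbol, 8 had several and 17108 had none, 39 of the named probes had no match in the RefSeq table, and no probe with several symbols was named. Of the tested probes, 12192 had a single gene and 3462 had none, and 9525 genes were represented by the tested probe with the highest mean over all arrays. Of 2170 genes with several tested probes, 367 had at least 1 probe past the threshold, in 120 of these all probes passed in 1 direction, and in 0 did probes pass in both directions. A bead array reports no read depth, and the number of arrays limits the precision.

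Samples were grouped by the labels into 7 baseline and 7 treated samples, and the sample titles give a baseline and a treated sample of each number, which was taken as the patient. After subtraction of the group means, the samples of a pair correlated at 0.252 to 0.610 over tested probes, the highest correlation between samples of different pairs was 0.178, and in 7 of 7 pairs each sample correlated best with its own partner. No 2 arrays held identical values, and normalized arrays correlated at 0.921 to 0.980. The main comparison was limma's moderated test of treated minus baseline with the patient as a block, which leaves 6 residual degrees of freedom, with Benjamini-Hochberg adjustment over all tested probes and an adjusted p threshold of 0.05. The series' design text names a paired t-test and significance analysis of microarrays (SAM), and both were run as alternatives.

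Before the data were examined, 33 gene lists of blood cell types, drug targets and immune pathways were fixed. Of these, 32 had at least 5 tested genes and were tested with camera at its preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over lists. The gamma delta T cell list had 1 tested gene and was not tested. Camera compares the genes of a list with all other genes, and with correlation estimated from the 14 arrays it allows for genes that vary together after the patient block. Correlation alone does not account for the higher p in that setting. The T cell activation and checkpoint list had an estimated correlation of 0.0076, under the preset, and its unadjusted camera p went from 7.0e-05 to 0.0068. The self-contained rotation test fry, which asks whether the genes of a list moved on balance in 1 direction, was a further alternative. Cell type lists name markers, and several markers are shared between cell types. The genes named in the text were the 15 largest rises and 15 largest falls past the threshold with the same direction in at least 6 of 7 pairs, up to 4 genes with the smallest p in each list, and MS4A1, CRBN, IKZF1, IKZF3, IRF4 and FOXP3 where tested, and a further gene set down with these is not reported here. Genes of the Y chromosome and XIST were left out of the tables of genes.

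Where a probe was not detected on any array of 1 group, its change is given as at least a fold, taken on the log2 scale as the mean of the bright group over the mean, per array of the dim group, of the higher of the lowest signal among detected probes and the probe's own signal. The analysis was tested on simulated data for the comparison of treated with baseline, over 15654 probes of which 200 were changed. It recovered 24% of changes of 0.5 and 88% of changes of 1 on the log2 scale, and 5.08% of its 118 calls were false. The simulated noise was drawn independently for each probe and held no difference in array brightness. These rates therefore do not give the share of false calls in the real data, where genes vary together. Alternatives were the fit without the block, the deposited signals on a log2 scale without normalization, no background correction, median scaling, an offset of 50, no filter and 2 stricter filters on dim probes, 1 probe per gene, the methods' t-test, SAM, array weights, each pair left out, another choice of probe for the lists, and other list tests. The fit with the array background as a covariate and an exact sign-flip test of each list over the pairs were added after seeing the data. Slide was not used as a block because the file headers name no slide. Figures were drawn with matplotlib.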

Results

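The data were 14 bead arrays of globin-cleared whole blood RNA, 7 from patients with follicular lymphoma at baseline and 7 from the same patients in the second cycle of lenalidomide with rituximab. Between 15199 and 17611 probes per array had a detection p under 0.05, with 16558 ± 961 at baseline and 16324 ± 393 in the treated samples (mean ± SD, n = 7). The arrays of the treated samples were brighter. The median signal of all probes was 79.5 ± 5.71 at baseline and 85.7 ± 3.24 after treatment, higher in the treated sample of 7 of 7 pairs (exact two-sided sign-flip p = 0.0156, the smallest that 7 pairs can give), while the number of detected probes was higher in 3 of 7 (exact p = 0.594).

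**Figure D1:**
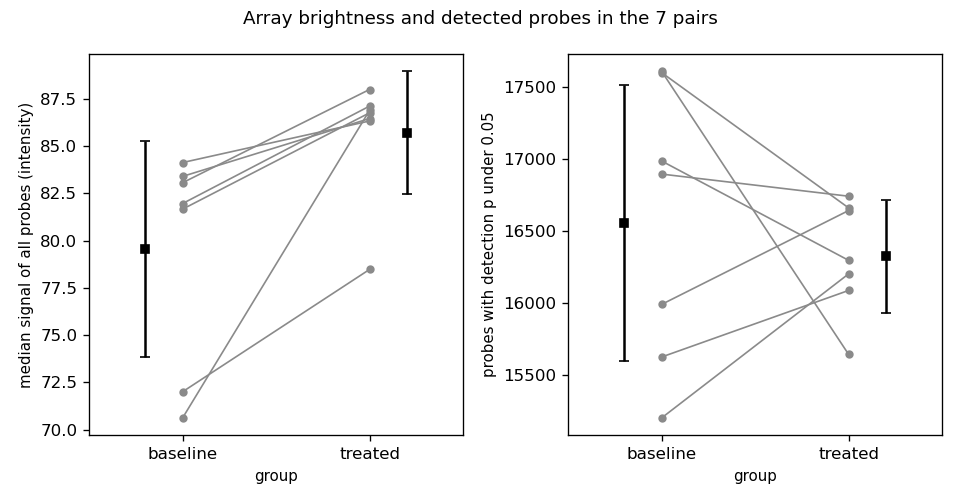
Median signal of all probes on each array (left, linear intensity) and the number of probes with a detection p under 0.05 (right) in the 7 baseline and 7 treated samples, with lines joining the samples of a patient and squares with bars giving mean ± SD. The median signal was higher in the treated sample of 7 of 7 pairs, and the axes do not start at 0.

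The comparison of treated with baseline samples asked how the combined treatment changed gene expression in the blood. Of 17 tested B cell genes 12 fell, among them the B cell receptor component CD79A, which fell 8.81-fold. Of 21 platelet, 22 mature neutrophil and 27 erythroid genes 18, 12 and 9 fell. These 3 lists were lower with camera's preset correlation (adjusted p = 0.19, 0.29 and 0.52 with an estimated correlation). The largest rise was that of the myeloid lectin receptor CLEC5A, 6.92-fold. Of 13 eosinophil genes 7 rose and of 16 T cell activation genes 5 rose (adjusted p = 0.29 and 0.19 for these lists with an estimated correlation). In limma's paired test 605 probes were higher and 959 lower at an adjusted p under 0.05, together 9.99% of the 15654 tested. At the level of genes 421 were higher and 620 lower, of which 50 and 66 changed at least 2-fold. Of the 1564 probes past the threshold, 1193 moved in their direction in 7 of 7 pairs and 1541 in at least 6. Without the block for patients the probes higher after treatment numbered 176 and the probes lower after treatment 226. On the deposited signals with neither background correction nor normalization, where the median change over all genes was 0.14 on the log2 scale against 0.02 after normalization, 2903 were higher and 581 lower.

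**Figure D2:**
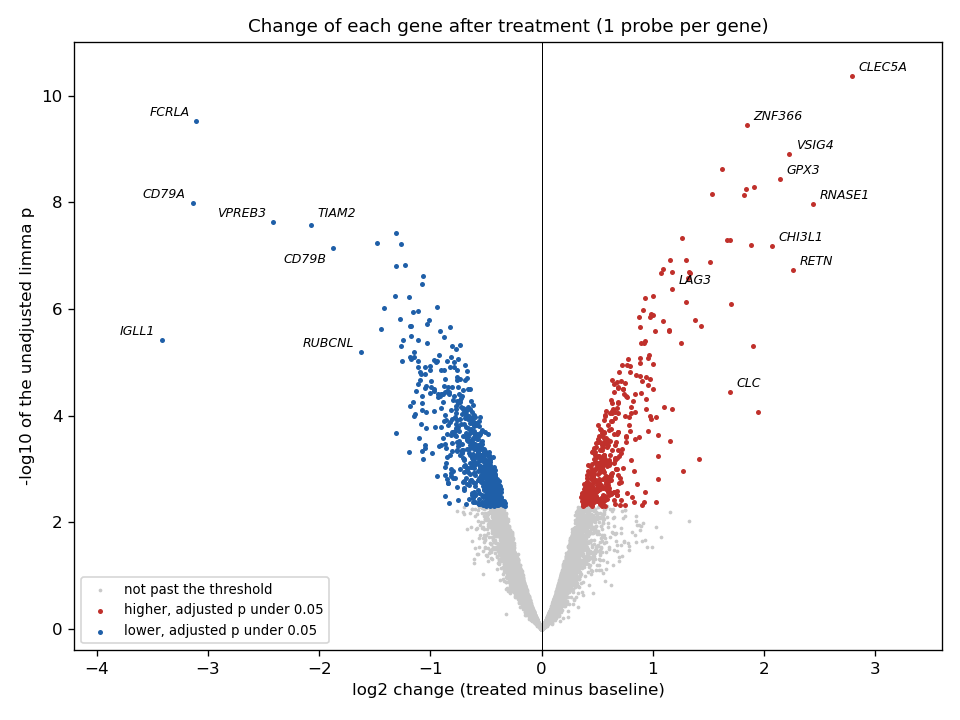
Log2 change from baseline to treatment of each gene (x axis, 1 probe per gene) against the negative log10 of its unadjusted limma p (y axis). Colours mark the 421 genes higher and 620 lower at an adjusted p under 0.05, with CLEC5A the largest rise and IGLL1 the largest fall.

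Of 17 tested genes of the B cell list, 12 fell, 0 rose and 5 did not pass, and the list's median change was -1.04 on the log2 scale, negative in 7 of 7 pairs (camera adjusted p = 5.9e-11, adjusted p = 0.19 with an estimated correlation). With the 4 of its genes that were undetected in a whole group set at their bounds the median was -0.85. With no filter on dim probes the median of the B cell list was -0.37. CD79A and CD79B, the signalling chains of the B cell receptor, changed by -3.14 ± 0.25 and -1.88 ± 0.17 (log2 change ± SE, n = 7 pairs, limma adjusted p = 1.2e-05 and 3.8e-05). FCRLA, a B cell Fc receptor-like protein, and VPREB3, a B lineage gene, were detected on 7 baseline arrays and on 0 treated arrays, and so were at least 4.76-fold and 3.22-fold lower (limma adjusted p = 1.9e-06 and 2.2e-05). IGLL1, an immunoglobulin lambda-like gene whose probe may also report related light chain transcripts, had the largest fall, -3.42 ± 0.45 (limma adjusted p = 5.6e-04). The long non-coding RNA LINC00926 was at least 1.72-fold lower and undetected in all treated samples. Adjusted over the list alone, 12 genes were lower and 1 higher, CD24 at 1.03, a surface protein also carried by neutrophils, which was named after its values were seen. CD20 itself could not be followed, as the 3 probes of MS4A1 were detected on at most 3 baseline and 2 treated arrays. The plasma cell list had a median of -0.12 over 8 genes, 0.04 on signals without normalization and 0.16 with array brightness as a covariate, and did not pass (adjusted p = 0.54). Its member MZB1, an endoplasmic reticulum protein of antibody-producing cells, fell by 0.75 on the log2 scale (limma adjusted p = 0.043) but stood at 0.12 with that covariate and at -0.49 without pair 1, and CD38 at 0.31 passed adjusted over the list alone. None of the 8 germinal centre B cell genes passed (adjusted p = 0.73), with BCL6 at -0.30 and MME at -0.34, and the list's mean was -0.04 while its median was 0.01.

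**Figure D3:**
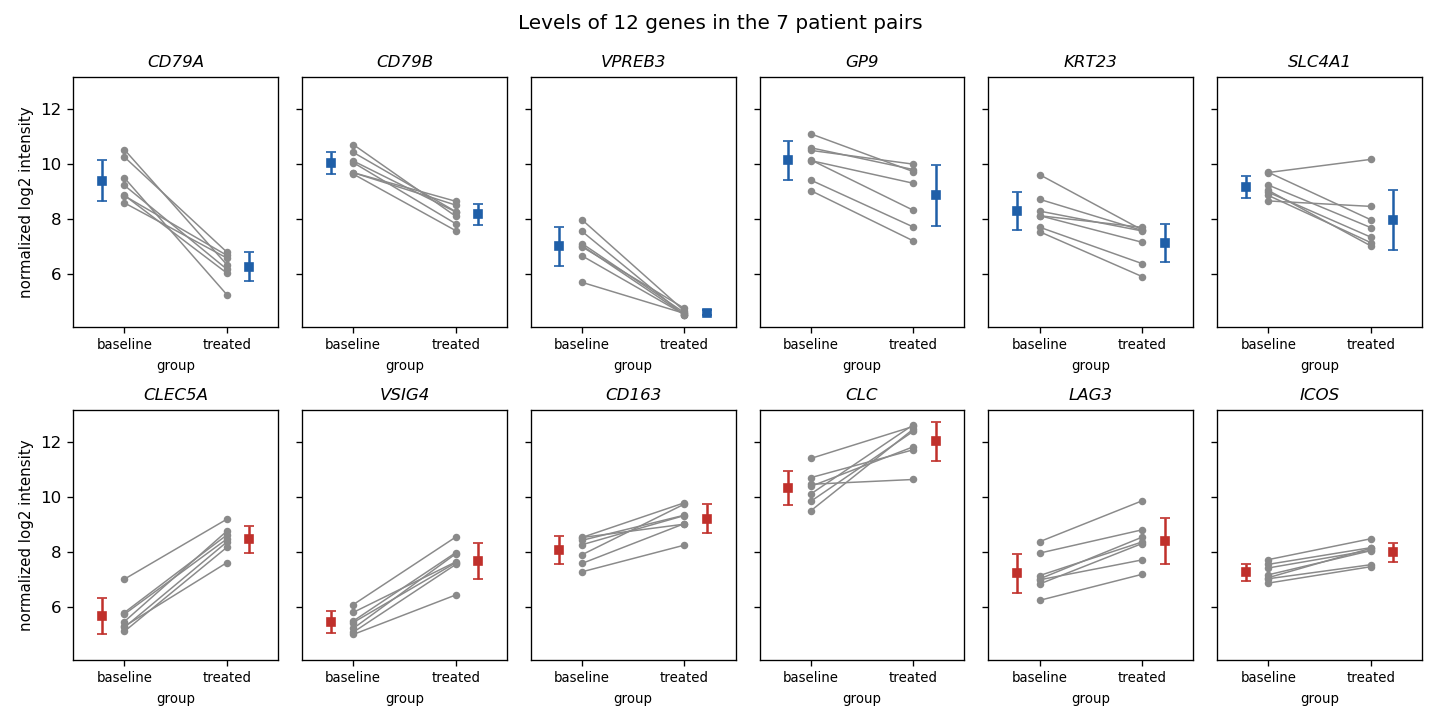
Normalized log2 intensity of 12 genes in the 7 baseline and 7 treated samples, with grey lines joining the samples of a patient and coloured squares with bars giving mean ± SD per group. CD79A, CD79B and VPREB3 are B cell genes, GP9 platelet, KRT23 neutrophil, SLC4A1 red cell, CLEC5A, VSIG4 and CD163 monocyte or macrophage, CLC eosinophil, and LAG3 and ICOS T cell genes, and 11 of the 12 moved the same way in 7 of 7 pairs, SLC4A1 in 6.

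The 15 largest rises ran from 3.24-fold for MCEMP1 to 6.92-fold for CLEC5A. CLEC5A rose from 5.67 ± 0.64 to 8.46 ± 0.49 (normalized log2 intensity, mean ± SD, n = 7; limma adjusted p = 6.7e-07). VSIG4, a complement receptor of macrophages, rose by 2.23 ± 0.15 (SE) and the scavenger receptor MARCO by 1.84 ± 0.14 (limma adjusted p = 4.9e-06 and 9.0e-06). CLEC10A, a lectin of dendritic cells and macrophages, rose by 1.91 ± 0.14, and ZNF366, a transcriptional regulator of dendritic cells, by 1.84 ± 0.11, with every other tested probe of both genes past the threshold in the same direction. The secreted products RETN (resistin), GPX3 (plasma glutathione peroxidase) and CHI3L1 (a chitinase-like glycoprotein) rose 4.79-fold, 4.41-fold and 4.19-fold. The ribonuclease RNASE1 was detected on 0 baseline and 7 treated arrays and was at least 3.51-fold higher. The remaining genes of this group were SLC2A5, a fructose transporter that rose in 6 of 7 pairs, MYBPH, TPM2, MCEMP1 and the pepsinogen genes PGA3 and PGA5, whose near-identical sequences 1 probe may not tell apart. These 6 rose by 1.70 to 1.95 on the log2 scale.

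Of 21 classical monocyte genes 4 rose, 1 fell and 16 did not pass, with a list median of 0.22 that was positive in 7 of 7 pairs (camera adjusted p = 0.014, adjusted p = 0.52 with an estimated correlation, and 0.059 without pair 7). Without pair 6 the median of the classical monocyte list was 0.15. The haemoglobin scavenger receptor CD163 rose 2.21-fold, the chemokine receptor CCR2 1.84-fold and the oxidase subunit CYBB 1.49-fold, while the protease inhibitor SERPINA1 fell 1.48-fold, with 1 of its 2 other probes past the threshold. CD36, named after its values were seen, rose by 0.52. Of the list, 8 were higher and 2 lower adjusted over the list alone. Of 12 non-classical monocyte genes 4 fell, 0 rose and 8 did not pass (median -0.33, camera adjusted p = 0.0085, adjusted p = 0.29 with an estimated correlation). These were the cell cycle inhibitor CDKN1C, which fell by 1.07 and in 5 of 7 pairs, LYPD2, MS4A7 and LILRA1. With p adjusted over the list alone 5 were lower and 1 higher. Of 11 conventional dendritic cell genes 4 rose (median 0.30, camera adjusted p = 0.0022, adjusted p = 0.19 with an estimated correlation): CLEC10A, the lipid antigen presenting molecule CD1B at 0.96, the IgE receptor chain FCER1A at 0.93 and NDRG2 at 0.41, and 5 passed adjusted over the list alone. The plasmacytoid dendritic cell list did not pass camera (7 genes, median -0.44, negative in 7 of 7 pairs, adjusted p = 0.14) but passed fry (adjusted p = 0.014). Its transcription factor TCF4 fell by 1.04 and EPHB1 was at least 1.46-fold lower, while GAS6, a ligand of TAM receptors, rose by 0.96. PTCRA, which the platelet list also holds, fell as well, and adjusted over the list alone 2 were higher and 4 lower.

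Of 16 genes of activation and checkpoint receptors 5 rose, 0 fell and 11 did not pass, with a median of 0.33 that was positive in 7 of 7 pairs (camera adjusted p = 3.2e-04, adjusted p = 0.19 with an estimated correlation). Of these genes 9 were higher adjusted over the list alone. The inhibitory receptor LAG3 rose by 1.17 ± 0.13 (SE, n = 7 pairs, limma adjusted p = 1.2e-04), the costimulatory receptors ICOS by 0.72 and TNFRSF9 by 0.68, and the checkpoint receptor CTLA4 by 0.46. CD69, named after its values were seen, rose by 0.66. In the T cell list 4 of 19 genes rose (median 0.20, camera adjusted p = 0.0010, adjusted p = 0.52 with an estimated correlation), ICOS, the adaptor TRAT1, CD2 and the T cell receptor chain CD3D, and 6 adjusted over the list alone. Without pair 6 the median of the T cell list was 0.11. The other probe of CD3D and that of CTLA4 did not pass. In the list of naive T cells LRRN3 and EPHX2 rose by 0.88 and 0.61 and ACTN1, a cytoskeletal gene also abundant in platelets, fell by 0.54. The list did not pass (13 genes, median 0.08, adjusted p = 0.12), and adjusted over the list alone 4 were higher and 1 lower.

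Of 20 cytotoxic and CD8 T cell genes 2 rose (median 0.16, camera adjusted p = 0.021, adjusted p = 0.59 with an estimated correlation), the homeobox gene HOPX by 1.00 and the protease GZMA by 0.69, the same 2 adjusted over the list alone. Of 22 NK cell genes 4 rose (median 0.21, camera adjusted p = 0.021, adjusted p = 0.58 with an estimated correlation), the receptors CD160, KLRD1, KLRC1 and KLRC3 by 0.55 to 0.73, also 4 adjusted over the list alone. KLRC1 and KLRC3 are close relatives whose probes may share signal. With the array median signal as a covariate the medians of these lists were -0.18 and -0.25 and neither passed. Pair 1 had the largest gain in that signal, from 70.6 to 86.9, and the highest change of both lists, 0.774 and 0.907. The covariate therefore does not separate brightness from pair 1. Without pair 1 the 2 medians were 0.06 and 0.14 and neither list passed. The regulatory T cell list did not pass (9 genes, adjusted p = 0.72, with a median of -0.04 that was 0.10 on signals without normalization, a mean of 0.01 and 2 higher and 1 lower adjusted over the list alone). In it CTLA4 rose and F5, a coagulation factor, fell by 0.86, and the lineage factor FOXP3 was too dim to test. Of 18 proliferation genes 1 rose, CDCA7 by 0.55, and the list did not pass (median 0.01, adjusted p = 0.80, with 0 past the threshold adjusted over the list alone).

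Of 22 mature neutrophil genes 12 fell, 0 rose and 10 did not pass, with a median of -0.61 that was negative in 7 of 7 pairs (camera adjusted p = 3.6e-10, adjusted p = 0.29 with an estimated correlation), and the same number passed adjusted over the list alone. KRT23 fell by 1.17 on the log2 scale, the histidine ammonia lyase HAL by 1.13, the transcription factor CREB5 by 1.07 and VNN2 by 0.87. For VNN2, 1 of 2 other probes had the opposite sign, and the other probe of HAL did not pass. Of 19 genes of immature neutrophil granules 3 rose (median 0.33, camera adjusted p = 0.011, adjusted p = 0.59 with an estimated correlation), haptoglobin (HP) by 1.43, the antimicrobial peptide CAMP by 1.41 and the protease CTSG by 1.27. The number past the threshold adjusted over the list alone was 4. This list was higher in 4 of 7 pairs, and without pair 2 or pair 4 its median was 0.17 or 0.16 and it did not pass, while without pair 6 the median was 0.66. Of 13 eosinophil genes 7 rose, 0 fell and 6 did not pass, with a median of 0.69 that was positive in 7 of 7 pairs (camera adjusted p = 1.2e-07, adjusted p = 0.29 with an estimated correlation), and 10 passed adjusted over the list alone. CLC, the Charcot-Leyden crystal protein, rose 3.23-fold, the transcription factor OLIG2 2.45-fold, the eosinophil ribonuclease RNASE2 2.26-fold and THBS4 1.61-fold. The basophil and mast cell list did not pass (9 genes, median 0.12, adjusted p = 0.20, with 2 higher adjusted over the list alone), and its 1 member to rise was FCER1A. With 1 pair left out at a time, the median of this list ran from 0.025 without pair 4 to 0.47 without pair 6. Its camera adjusted p ran from 0.0030 to 0.43 over these fits. Of 7 haematopoietic progenitor genes none passed over all probes (median -0.13, and 0.04 on signals without normalization, adjusted p = 0.40), with MYB at 0.55 and SMIM24 at -0.53 past the threshold adjusted over the list alone.

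Of 21 platelet genes 18 fell, 1 rose and 2 did not pass, with a median of -0.84 that was negative in 7 of 7 pairs (camera adjusted p = 1.2e-13, adjusted p = 0.19 with an estimated correlation), and 19 were lower and 1 higher adjusted over the list alone. The adhesion receptor subunit GP9 fell by 1.27 ± 0.17 on the log2 scale (SE, n = 7 pairs, limma adjusted p = 6.7e-04), PTCRA by 1.25, NRGN by 1.17 and CTTN by 0.81. The member that rose was SPARC, a matrix protein of platelets and many other cells, by 0.60, named after its values were seen. Of 27 erythroid and reticulocyte genes 9 fell, 0 rose and 18 did not pass (median -0.51, negative in 5 of 7 pairs, camera adjusted p = 9.7e-06, adjusted p = 0.52 with an estimated correlation), and adjusted over the list alone 14 were lower and 1 higher. The red cell anion exchanger SLC4A1 fell by 1.19, the haemoglobin mu chain HBM by 1.15, and the membrane skeleton genes DMTN and EPB42 by 1.08 and 0.98. The median of 8 haemoglobin genes, whose transcripts the clearing step removes and whose probes may share signal, was -0.01, and that of the other 19 genes was -0.63.

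**Figure D4:**
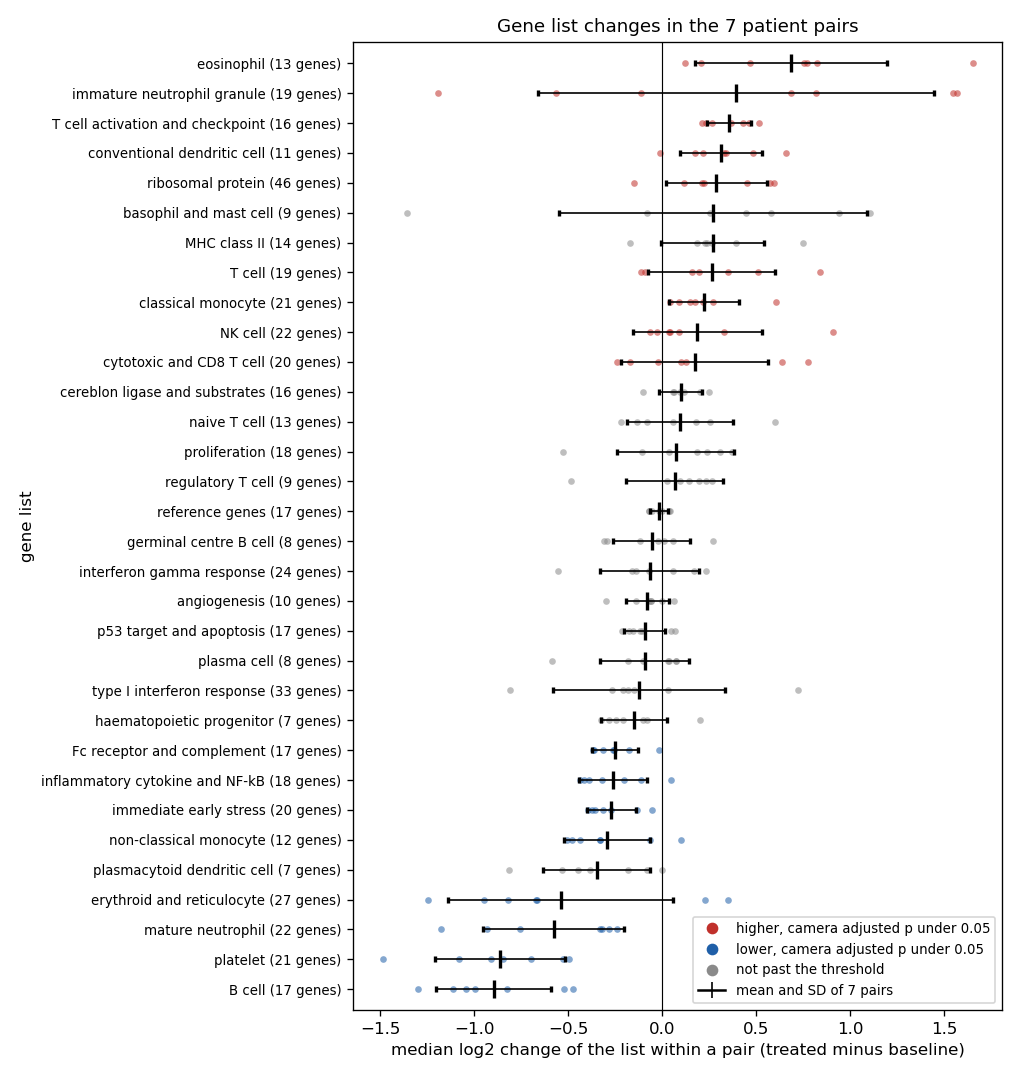
Median log2 change of 32 gene lists (y axis, with the number of tested genes) within each of the 7 pairs (x axis, treated minus baseline), where points are pairs and black bars give mean ± SD. Red and blue lists passed camera with its preset correlation of 0.01, and with an estimated correlation none did. The B cell, platelet and mature neutrophil lists were negative and the eosinophil and T cell activation lists positive in 7 of 7 pairs.

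Of 16 genes of the cereblon ligase and its substrates 2 rose, 1 fell and 13 did not pass (median 0.06, camera adjusted p = 0.39, fry adjusted p = 0.015), and 3 were higher and 1 lower adjusted over the list alone. The zinc finger gene ZNF692 rose by 0.91 ± 0.11 (SE, n = 7 pairs, limma adjusted p = 2.4e-04) and cereblon itself, CRBN, by 0.43 ± 0.12 (limma adjusted p = 0.032), although its second probe did not pass. BSG, a surface glycoprotein that binds cereblon, fell by 0.67. The transcription factors IKZF1 and IKZF3, substrates that lenalidomide directs to cereblon for degradation, were at 0.35 ± 0.12 and -0.19 ± 0.17 (limma adjusted p = 0.078 and 0.51), the latter at 0.01 on signals without normalization, and IRF4 was too dim to test. Degradation acts on the proteins, which these RNA levels do not measure.

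Of 18 genes of inflammatory cytokines and NF-kB signalling 6 fell, 2 rose and 10 did not pass (median -0.13, camera adjusted p = 0.014, adjusted p = 0.38 with an estimated correlation), and on signals without normalization the median was 0.01. The cytokine IL1B fell by 1.18, RELB by 0.84, BCL3 by 0.69 and NFKBIZ by 0.63, while CXCL1 and TNF, named after their values were seen, rose by 0.80 and 0.41. Of 20 immediate early and stress genes 6 fell and 1, CD69, rose (median -0.24, camera adjusted p = 0.0020, adjusted p = 0.29 with an estimated correlation), with FOS at -0.88, DUSP1 at -0.77, IER3 at -0.50 and JUNB at -0.48. Of 17 Fc receptor and complement genes 6 fell, 0 rose and 11 did not pass (median -0.33, camera adjusted p = 0.011, adjusted p = 0.29 with an estimated correlation, and 0.068 with array brightness as a covariate), with CR1 at -0.72, FCGR2B at -0.70, FCGR3B at -0.62 and CFD at -0.59. Neither the 2 other probes of FCGR2B nor the other of FCGR3B passed, and 1 of 2 did for CR1. FCGR3B and CR1 are abundant in neutrophils. Without pair 2 the median of the Fc receptor and complement list was -0.22, and the inflammatory list ran from -0.20 without pair 7 to -0.09 without pair 5. Adjusted over the list alone the numbers lower and higher were 8 and 2, 9 and 1, and 9 and 2 in these 3 lists.

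Of 33 type I interferon genes 4 fell, 0 rose and 29 did not pass (median -0.07, adjusted p = 0.12), with ISG20 at -0.74, OASL at -0.71, MX2 at -0.47 and IFITM1 at -0.42. On signals without normalization the list had a median of 0.09 and camera adjusted p = 0.020. That median lies below the 0.14 of all genes in that setting, so it does not show a rise of the list. The other probe of OASL did not pass. Without pair 6 this list passed with a median of -0.24, and without pair 2 its median was 0.07. Of 24 interferon gamma genes 1 rose and 3 fell (median -0.08, and 0.05 on signals without normalization, mean 1.9e-04, adjusted p = 0.48), the complement inhibitor SERPING1 at 1.10 and AIM2, GBP2 and WARS1 at -0.81, -0.47 and -0.44. The type I genes lower adjusted over the list alone numbered 6, and 4 interferon gamma genes were higher and 5 lower. MHC class II genes divided: HLA-DMA rose by 0.52 and HLA-DRB4 by 0.55, as did HLA-DRB1 and HLA-DMB, both named after their values were seen, while the B cell genes HLA-DOB and HLA-DOA fell by 1.18 and 0.57 (14 genes, list median 0.27, adjusted p = 0.060, with 5 higher and 2 lower adjusted over the list alone). The DRB genes are near-identical and differ between people, so their probes are uncertain. Of 2 other HLA-DRB4 probes 0 passed and 1 had the opposite sign. With 1 pair left out at a time, the median of the MHC class II list ran from 0.18 without pair 6 to 0.35 without pair 2. Its camera adjusted p ran from 0.012 to 0.17 over these fits. Of 17 p53 target and apoptosis genes 3 fell, BCL2L1 by 0.90, FAS by 0.47 and MCL1 by 0.43 (median -0.12, and 0.03 on signals without normalization, adjusted p = 0.39, with 2 higher and 4 lower adjusted over the list alone). None of 10 angiogenesis genes passed (median -0.13, and 0.05 on signals without normalization, adjusted p = 0.45), with VEGFA at 0.34. Of 46 ribosomal protein genes 1 rose, RPL4 by 0.41, and 45 did not pass, with 0 adjusted over the list alone and a list median of 0.29, positive in 6 of 7 pairs (camera adjusted p = 3.7e-06, adjusted p = 0.52 with an estimated correlation). Of 17 reference genes 1 passed, POLR2A at -0.56, also adjusted over the list alone, and the list's median was -0.01, and 0.13 on signals without normalization (adjusted p = 0.63).

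Among the largest falls not named above were TIAM2, an activator of Rac, at -2.07 ± 0.18 and RUBCNL, an autophagy gene, at -1.62 ± 0.22 (SE, n = 7 pairs, limma adjusted p = 2.4e-05 and 8.4e-04). Which blood cells these falls came from was not tested. The vasodilator peptide gene ADM stood at -1.48, the adhesion molecule JAM3 at -1.44, the channel gene PANX2 at -1.42, ZMYND15 at -1.32 and C10orf105, KRT1 and TMEM140 at -1.31 each, KRT1 in 6 of 7 pairs.

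With camera's preset correlation 9 lists were higher and 8 lower, with an estimated correlation none held a call, and fry kept 11 of the 17 and added 2. All samples were whole blood, so a change may follow the share of a cell type or its expression, and no untreated or single-drug patients were analysed here.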

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

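The tests of a larger monocyte share, of dim probes among those detected on all arrays, of uneven globin clearing and of a lower neutrophil share alone were chosen after the results were seen. The other tests were set down before their own values were seen. Of these, the tests of array brightness and of macrophage-associated genes were added after the main results. Of 188 sets of 7 values, 16 had 1 value far from the other 6, where chance gives about 9.4.

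The 15 largest rises included the macrophage genes VSIG4 and MARCO. The classical monocyte list had a median change of 0.224 with a 95% bootstrap upper limit, over its genes and not over patients, of 0.330. That lies below the smallest of the 15 rises at 1.70, but the choice of the largest rises nearly fixes that order. A larger share of classical monocytes is therefore not excluded by it. With array brightness as a covariate the median change of the 15 rises was 1.91 with a median SE of 0.268, and 15 of 15 still passed. That argues against a change in proportion to brightness. The treated array was brighter in 7 of 7 pairs, however, so an effect shared by all treated arrays is not excluded. Of the 15 probes 14 were detected on all 7 treated arrays, but the choice of the largest rises nearly fixes that number, so it excludes nothing. For 8 of the rises the probes were detected on all 14 arrays, and so were above the negative controls at baseline too. Their smallest change minus 2 SE was 1.25, but the choice of large changes past the threshold nearly fixes such a value. Noise of dim probes is thus not excluded by it and stays open, most of all for the other 7. A broad rise of macrophage-associated genes stays open as well.

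The platelet list was lower in 7 of 7 pairs and the erythroid list in 5 of 7 (adjusted p = 0.19 and 0.52 with an estimated correlation). Uneven globin clearing is argued against for the platelet list, whose genes the step does not target. Its pair medians were -0.86 ± 0.35 (mean ± SD, n = 7). The platelet genes had a median of -0.840 (95% bootstrap upper limit -0.584). The 19 erythroid genes other than haemoglobins had a median of -0.633 (upper limit -0.498). These limits resample genes, which vary together, and do not measure the spread between patients. The erythroid list was positive in 2 of 7 pairs, so uneven clearing is not excluded for it. Dilution of both by more leukocyte RNA would lower both lists alike. The platelet list fell further by a mean of -0.323 ± 0.362 (SD, n = 7 pairs, exact two-sided sign-flip p = 0.0625). The erythroid pair medians in this test included the 8 haemoglobin genes, which the clearing step removes and which may narrow the erythroid fall. Dilution therefore cannot be told apart from separate changes with 7 pairs. Over the pairs the 2 changes had Pearson r = 0.840 (exact permutation p = 0.0167, adjusted over 4 such relations 0.0667) and Spearman rho = 0.750 (exact p = 0.0663, adjusted 0.133), with r = 0.740 without the 2 farthest pairs.

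The mature neutrophil list was lower in 7 of 7 pairs and the immature granule list higher in 4 of 7 (adjusted p = 0.29 and 0.59 with an estimated correlation). A lower share of neutrophils alone is argued against, since it would raise the markers of all other types, and the pair medians of the platelet list were -0.86 ± 0.35 and those of the eosinophil list 0.69 ± 0.51 (mean ± SD, n = 7), while by camera's preset correlation 6 other cell type lists were higher and 3 besides B cells lower, calls that were lost with an estimated correlation. For younger circulating neutrophils the 2 lists were set to run oppositely over the pairs, and they ran in parallel with Spearman rho = 0.786 (exact permutation p = 0.0480, adjusted over 4 relations 0.133) and Pearson r = 0.723 (exact p = 0.0802, adjusted 0.160), with r = 0.763 without the 2 farthest pairs. A neutrophil share that differs between patients would move both lists alike at any age of the cells, so that test excludes nothing. Younger neutrophils, a change within neutrophils and shifts of several cell types at once stay open.

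Of the other 2 relations computed, mature neutrophil and T cell changes had r = -0.498 and rho = -0.250 (exact permutation p = 0.255 and 0.595, adjusted 0.340 and 0.783, r = -0.665 without the 2 farthest pairs), and T cell and ribosomal changes r = 0.109 and rho = -0.143 (exact permutation p = 0.813 and 0.783, adjusted 0.813 and 0.783, r = -0.542 without them).

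In pair 1 the plasma cell list stood at -0.588 against -0.182 to 0.0721 in the others, the NK cell list at 0.907 against -0.0678 to 0.330, MZB1 at -2.33 and EPHB1 at -1.99. The regulatory T cell list stood at -0.488 in pair 5 against 0.0271 to 0.264 in the others, where ADM stood at -2.28. In pair 6 SLC2A5 stood at -0.791 against 1.36 to 2.83 in the others, CTSG at -1.16 against 1.22 to 2.27, CLEC10A at 2.77, MARCO at 2.65, GAS6 at 2.27, RUBCNL at -3.30 and F5 at -2.15. In pair 7 the classical monocyte list stood at 0.605 against 0.0395 to 0.268 in the others, ISG20 at -1.01, and the treated array had a median signal of 78.5 against 86.3 or more.

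Of the 64 splits that part all 7 pairs, 1, the real one, gave 1564 probes past the threshold, 605 higher or 959 lower. The highest other count was 2. That argues against chance regrouping for the probe counts, although 1 of 64 is the strongest result these splits can give. The real split also parts the brighter from the dimmer array in 7 of 7 pairs, so it does not separate treatment from brightness. The B cell median of 1.04 in size was reached by 1 split, with 0.897 the highest other, in a split that swaps 1 pair. The count of 17 lists past the threshold was reached by 2 of 64 splits, and the highest other count was 18, with 3 pairs swapped. The median over the 63 other splits was 10 lists by camera with its preset correlation. Splits with few pairs swapped keep part of the treatment difference, so these counts do not separate it from differences between patients.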

How the results depend on the processing

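The fit with array brightness as a covariate and the sign-flip test of lists were chosen after seeing the data, and the other alternatives before. The B cell list kept its direction in every alternative run, from -0.366 without a filter on dim probes to -1.13 without pair 3, but its adjusted p was 0.190 with camera's estimated correlation and 0.0556 in the exact sign-flip test, both at a median of -1.04. Those 2 tests gave 0 lists higher and 0 lower. By design 7 pairs give no sign-flip p under 0.0156, so over 32 lists a call needs at least 11 lists at that value, and 9 reached it. Thus the missing sign-flip calls do not count against those 9 lists. Among the other lists that passed camera, the unadjusted exact sign-flip p ran from 0.03125 for conventional dendritic cells to 0.375 for cytotoxic and CD8 T cells. It was 0.344 for immature granules, and the pairs of these last 2 lists were divided. With fry 5 lists were higher and 8 lower, among them the cereblon and plasmacytoid dendritic cell lists, which did not pass camera. Counts of probes higher after treatment and probes lower after treatment were 176 and 226 with no replicate block, all 402 among the 1564, 274 and 392 in the methods' t-test after adjustment (1775 and 1965 at an unadjusted p under 0.05), 368 and 588 with no filter, 847 and 1446 in SAM, and 468 and 283 with array brightness as a covariate, which kept 440 of the 1564. Without each pair in turn they ranged from 381 to 907 and from 580 to 941, and moved over 1.5 times without pair 3 (403 higher), pair 5 (381 and 580) and pair 7 (402 higher). On the deposited signals without normalization there were 2903 and 581 probes and 5 gene lists higher after treatment, and 11 values turned positive with the median over all genes at 0.14: plasma cell list 0.0429, regulatory T cell list 0.0975, haematopoietic progenitor list 0.0388, type I interferon response list 0.0866, interferon gamma response list 0.0513, inflammatory cytokine and NF-kB list 0.0112, p53 target and apoptosis list 0.0348, angiogenesis list 0.0457, reference genes list 0.133, ANGPT1 0.0058 and IKZF3 0.0119. With array brightness as a covariate the plasma cell list was 0.160, cytotoxic and CD8 T cell list -0.175, NK cell list -0.253, regulatory T cell 0.131, interferon gamma 0.0576, MZB1 0.120, TXNDC5 0.257 and TK1 0.0756. The reference list was 0.0350 with median scaling, 2.09e-05 with probes detected on all 14 arrays and 0.0525 with the most variable probe per gene, where the germinal centre B cell list was -0.0202. Without each pair in turn the medians ranged from -0.182 to 0.00319 (plasma cell), -0.0208 to 0.0683 (regulatory T cell), -0.0377 to 0.0180 (reference), -0.0380 to 0.0361 (germinal centre), -0.245 to 0.0703 (type I interferon) and -0.0220 to 0.133 (proliferation). Of 114 named genes past the threshold, 50 kept their call with no replicate block, 64 in the methods' t-test, 60 with array brightness, 83 with no filter, and 97 to 110 with a pair left out. The fit without the block also ended the list calls of cytotoxic T cells, NK cells and immature granules and no other. The causes were not tested. Fewer pairs or more probes tested tend to lower a count, yet without pair 1 the probes higher numbered 907, against 605 with all pairs. Slide as a block was not run. Signal over background limits dim genes such as MS4A1.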

Other observations

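The test of macrophage genes was set down after the largest rises were seen and before its own values were.

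A further list of 48 macrophage-associated genes, none of them named in the comparison, had 18 tested members, of which 6 rose, 2 fell and 10 did not pass limma's threshold, and the list did not pass camera at a threshold of 0.05. The formyl peptide receptor FPR3, undetected on all baseline arrays, was at least 1.63-fold higher. The scavenger receptor STAB1 rose 2.01-fold, the sterol-sensing nuclear receptor NR1H3 1.90-fold, the lysosomal lipase LIPA 1.71-fold, the transcription factor MAF 1.58-fold and the matrix protein TGFBI 1.51-fold, each in 7 of 7 pairs. The chemokine CXCL16 fell by 1.03 on the log2 scale and the haem-degrading enzyme HMOX1 by 0.69, each in 7 of 7 pairs as well.

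The hypothesis that macrophage-associated genes rose broadly is not settled by this list. Its median change was 0.130, with 95% bootstrap limits over its genes from -0.0678 to 0.594 that include the bound of 0.5 set for it. The mean of the pair medians was 0.23 ± 0.19 (SD, n = 7), positive in 7 of 7 pairs (exact two-sided sign-flip p = 0.0156, the smallest possible). A rise of some macrophage genes beside a fall of CXCL16 and HMOX1 may point to a selective change rather than a general one, which sorted monocytes could test.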
